A study of Zea mays with 2 samples.

How the data were processed

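Endosperm RNA of maize (Zea mays) kernels at 15 days after pollination was sequenced from wild type and from the defective kernel mutant dek33. The files hold 1 sample per genotype. Per the labels, the design was in triplicate, and how libraries became 1 value per gene and genotype is not given in the sources used here. Each sample was placed in its group by its genotype label.

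The FPKM values, fragment counts scaled for transcript length and library size, are those the authors deposited, 1 per gene and library. Per the submitters' processing notes, Bowtie 0.12.2 and the B73 RefGen_v3 assembly were used. The program that computed FPKM, the annotation release, the filters and the pooling of replicates are not given in the sources used here. Both files list the same 33283 genes in the same order. An FPKM of 1e-05 stands in the place of 0: 1330 genes had it in the dek33 library and 2022 in the wild type library, counting 1 value below it. Several of the most abundant genes of 1 library carry that value in the other, so it can mark a failed estimate. Such a gene is described as listed at 0, and no fold is given against it. FPKM carries no read counts. Ratios between low values were smooth: among 4314 genes below 0.3 FPKM in both libraries, no bin of 0.05 log2 units held more than 2.2% of genes. Sequencing depth is therefore unknown, and no counting interval or detection floor is given.

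Gene names come from the descriptions in the files and from a RefSeq gene table of the NAM-5.0 assembly, used for names only, which matched 18173 gene IDs (54.6%). Coordinates are those of the files. Starts were taken to count from 0 and were raised by 1, because 69.7% of 841 short predicted models then span a multiple of 3 bases, against 14.4% otherwise. Of all genes, 1878 share a printed locus with another gene, so a locus can cover neighbours. Zeins and other families of near-identical copies can exchange reads, and their single values are uncertain.

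The comparison used log2((dek33 + 1)/(wild type + 1)), a scale that understates the change of low genes. With 1 value per genotype there is no test, no replicate check and no p-value. Differences compare these libraries, not the genotypes. A gene was counted as higher or lower at a difference of at least 2-fold on this scale with an FPKM of at least 5 in 1 or both libraries. The 23 gene lists, the size rule, the alternatives and the rule for named genes were fixed before the data were examined. Named genes were the 15 highest and the 15 lowest ratios among genes with a name and an FPKM of at least 20, all genes of the riboflavin list, the 10 highest genes in wild type, and in every other list the 2 highest, the 2 lowest and the 2 most abundant members. Genes chosen after their values were seen are marked as such.

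For each list the median log2 ratio of members with an FPKM of at least 1 in 1 or both libraries was ranked among 10000 random lists. These had the same size and were drawn with replacement within 20 bins of mean expression. The percentile describes these libraries. Intervals of a median are exact binomial 95% intervals over list members, which are genes and not replicates. Because the median of all expressed genes was itself shifted, centred ratios have that median subtracted. Some fixed word patterns took in wrong genes or missed a member. Results are given for the lists as fixed, and corrected lists form an added alternative.

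The alternatives were pseudocounts of 0.1 and 5, other filters on low values, centring, scaling to a trimmed mean of M values (30% of M and 5% of A trimmed on each side), to the upper quartile, or to equal totals without zeins, and a limit of 4-fold. The procedure was tested on simulated data for the dek33 against wild type comparison with 33283 genes. With 200 genes changed 4-fold and log2 noise of 0.3 (SD) per library, 95.5% of changed genes were recovered and 1.23% of unchanged genes were called. Of 200 random unchanged lists, 13 fell outside the middle 95% of random medians. The noise was a chosen setting, the simulated libraries had no overall shift, and genes varied independently of each other. These rates therefore check the procedure and are not error rates of the counts and lists in these data. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.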

Results

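Endosperm, the starch- and protein-storing tissue of the maize kernel, was profiled by RNA sequencing at 15 days after pollination in wild type and in dek33, a defective kernel mutant. The data hold 1 library value per gene and genotype, in FPKM, so no difference has a replicate check and the values compare these libraries rather than the genotypes. The libraries are named by their labels. FPKM summed to 761571 in the dek33 library and to 672660 in the wild type library, and the number of reads behind them is unknown. Of 33283 genes, 20692 had an FPKM of at least 1 in the dek33 library and 19860 in the wild type library.

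The comparison asks how the endosperm transcriptome differs when the dek33 gene is mutated. The gene is known to encode PyrR, a pyrimidine reductase of riboflavin synthesis. PyrR (GRMZM2G090068, chromosome 5, 160118507 to 160129431, B73 RefGen_v3) had an FPKM of 6.44 in the dek33 library and 4.55 in the wild type library. Its centred log2 ratio was -0.018, so PyrR did not stand apart from the shift of all expressed genes. The nature of the mutation is not given in the sources used here, and a transcript can persist in a mutant, so these values do not check the labels. The list of riboflavin and flavin cofactor synthesis, the pathway to FMN and FAD, had 3 of 6 genes with an FPKM of at least 5 higher in dek33 and 0 lower. The fixed word pattern missed PyrR and took in pyrroline-5-carboxylate reductase (92.3 against 43.0), pyrrolidone carboxyl peptidase (41.9 against 40.6) and pyrroline-5-carboxylate synthetase (2.89 against 3.45), which are not riboflavin enzymes. The corrected list had 2 of 5 higher and 0 lower and stood at percentile 87.3. Riboflavin synthase alpha chain (GRMZM2G009196) had 7.22 against 2.95 and riboflavin kinase (GRMZM2G166931) 8.09 against 3.49. Both lumazine synthase genes (GRMZM2G033219 and GRMZM2G143480) differed less, 1.46-fold and 1.33-fold higher in dek33. Their centred log2 ratios were 0.058 and -0.058, near the median of all expressed genes. None of the 6 genes of the list as fixed passed 2-fold after centring, and its median centred log2 ratio of 0.19 stood at percentile 84.6 of random lists.

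Most genes had higher FPKM in the dek33 library. The median log2 ratio of the 21688 genes with an FPKM of at least 1 in 1 or both libraries was 0.44, a factor of 1.36, and log2 ratios below are given relative to it unless stated. By the deposited values, 2118 genes were at least 2-fold higher in the dek33 library and 577 lower, so that 78.6% of these were higher. Centred on the median, 632 were higher and 974 lower, or 39.4% higher. The direction of the majority thus depended on the scaling. The plot of all genes shows this shift.

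**Figure D1:**
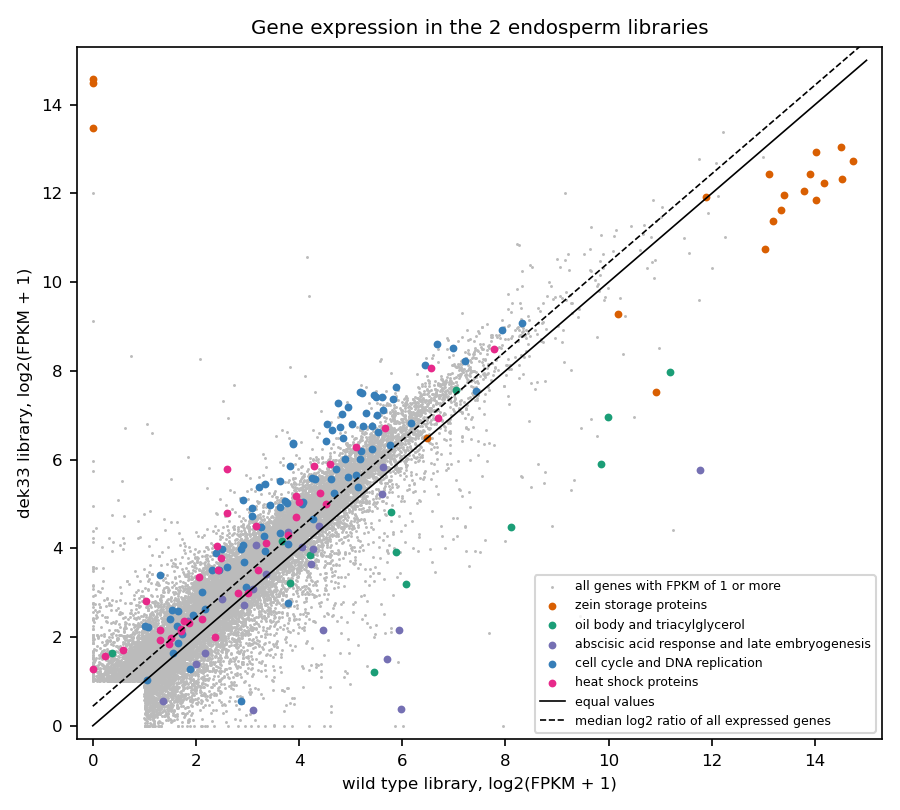
Each point is a gene, with log2(FPKM + 1) in the wild type library on the x axis and in the dek33 library on the y axis. Grey points are all genes with an FPKM of at least 1, and colours mark 5 of the gene lists. The dashed line lies 0.44 above the line of equal values. Most zein points lie far below both lines, and 3 zeins listed at 0 in wild type lie on the left edge.

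Zeins, the main storage proteins of maize endosperm, had lower values in the dek33 library. Of the 20 measured zein list members, 13 were lower by at least 2-fold, 3 higher and 4 neither, and after centring 15 were lower and 3 higher. The zein list median was -1.91 (interval over members -2.37 to -1.12), below each of the 10000 random lists. Alpha zein A30 (GRMZM2G353268), the most abundant gene of the wild type library, had 6794 in dek33 against 27300 in wild type, 4.02-fold lower. Alpha zein 19A2 (GRMZM2G008341) had 5162 against 23556, and alpha zein PZ22.1/22A1 (GRMZM2G397687) 8396 against 23340. The 3 higher members, alpha zeins A20, 19C2 and PMS2, had 24482, 22884 and 11333 in the dek33 library and were listed at 0 in wild type. Without them the median was -2.15. The gamma zein gz50, outside the list, had 4099 and was likewise listed at 0 in wild type. The 3 alpha zeins belong to families of near-identical copies. Their values at 0, and that of gz50, may not be absence of the transcript. Zeins together made up 16.7% of summed FPKM in the dek33 library and 31.2% in wild type. Zein FPKM summed to 126956 in the dek33 library and 210087 in wild type, 1.65-fold lower in dek33. The 3 members listed at 0 in wild type carried 58699 of the dek33 sum. Leaving them out takes FPKM from the dek33 library alone and gives 68257 against 210087, 3.08-fold.

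Several genes of oil bodies, the lipid stores of embryo and aleurone, were lower in the dek33 library. Of 12 oil body and triacylglycerol genes with an FPKM of at least 5, 7 were lower, 0 higher and 5 neither (9 lower and 0 higher after centring), and the median was -2.41 (interval over members -4.07 to 0.06), below each of the random lists. Oleosin Zm-I (GRMZM2G337229), a structural coat protein of oil bodies, had 251 in dek33 against 2332 in wild type, 9.31-fold lower. Oleosin ole17 (GRMZM2G480954) had 58.3 against 922, oleosin Zm-II (AC206941.2_FG002) 123 against 1015, and steroleosin (GRMZM2G108338) 1.33 against 42.9. Diacylglycerol O-acyltransferase 1 (GRMZM2G042356), an enzyme of triacylglycerol synthesis, had 17.0 against 11.7, and caleosin (GRMZM2G342685) had 190 against 131. Fatty acid synthesis genes had a median of -0.26 at percentile 0.4, while their median before centring was 0.18. The word pattern of this list was broad and took in a 3-ketoacyl-CoA synthase (GRMZM2G445602), which is among its lower genes. No corrected version of it was made. Of 23 such genes at 5 FPKM or more, 3 were higher and 4 lower before centring, and 0 higher and 4 lower after it. The 4 expressed fatty acid beta oxidation genes had a median of -1.02 at percentile 0.53, although none of 3 genes at 5 FPKM or more differed by 2-fold before centring and 1 was lower after it.

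Several genes of late seed maturation also had lower values in dek33. Of 18 genes of the abscisic acid response and late embryogenesis list with an FPKM of at least 5, 6 were lower and 0 higher (7 and 0 after centring), and the median was -0.77 (interval -2.75 to -0.32), below each of the random lists. Before centring it was -0.33 with an interval of -2.31 to 0.12. EMB564 (AC233879.1_FG002), a late embryogenesis abundant protein, had 53.2 in dek33 against 3482 in wild type, 65.4-fold lower. LEA D-34 (GRMZM2G025857) had 0.291 against 62.2. Other members went the other way or differed little, with GRMZM2G000777 at 15.8 against 7.98, GRMZM2G004349 at 19.5 against 12.9 and GRMZM2G031308 at 55.7 against 48.6, and 12 of the 18 were neither higher nor lower. Outside that list, globulin-2 (GRMZM2G026703, chromosome 1, 287133859 to 287135934), an embryo storage protein, had 4.53 against 700, 154-fold lower. The seed-specific vacuolar aquaporin TIP3-1 (GRMZM2G305446) had 21.5 against 475, and the antimicrobial peptide MBP-1 (GRMZM2G325118) 20.3 against 2448. The carotenoid and abscisic acid synthesis list did not stand apart, with a median of -0.16 at percentile 21.1. Within it, beta-carotene hydroxylase 1 (GRMZM2G152135) had 410 against 166. The word pattern also took in viviparous-1 (GRMZM2G133398), a transcription factor of seed maturation and not a synthesis enzyme, which had 5.86 against 12.7.

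Among the highest ratios of named genes not listed at 0 were those of glutathione transferases, an alternative oxidase and a mitochondrial import subunit. Glutathione transferase GSTU6 (GRMZM2G025190, chromosome 1, 81450790 to 81452151) had 322 in dek33 against 0.667 in wild type. Alternative oxidase (GRMZM2G125669, chromosome 2, 12345073 to 12348033), a mitochondrial enzyme that passes electrons to oxygen without the cytochrome pathway, had 104 against 0.551. Glutathione transferases gst41 (GRMZM2G097989) and GST4 (GRMZM2G132093) had 203 against 5.68 and 158 against 4.72. The small heat shock protein gene hsp22 (GRMZM2G007729) had 272 against 13.2, and the mitochondrial import subunit TIM14 (GRMZM2G029385) 65.4 against 2.58. The 12-oxophytodienoate reductases opr2 and opr1 had 25.7 in dek33, against 0.301 and 0.529 in wild type. Another alternative oxidase gene, GRMZM2G102349, had 17.2 against 16.9, and the alternative respiration list as a whole, with 4 expressed genes, had a median of 0.10 at percentile 61.9. That median turned with the settings, from 3.05 uncentred over the 2 genes with at least 5 FPKM to -0.42 by trimmed mean scaling. It shows no direction. Complex I and II genes had a median of 0.27 (interval 0.15 to 0.44) at percentile 84.3, with 2 of 17 higher and 0 lower before centring and none after it.

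**Figure D2:**
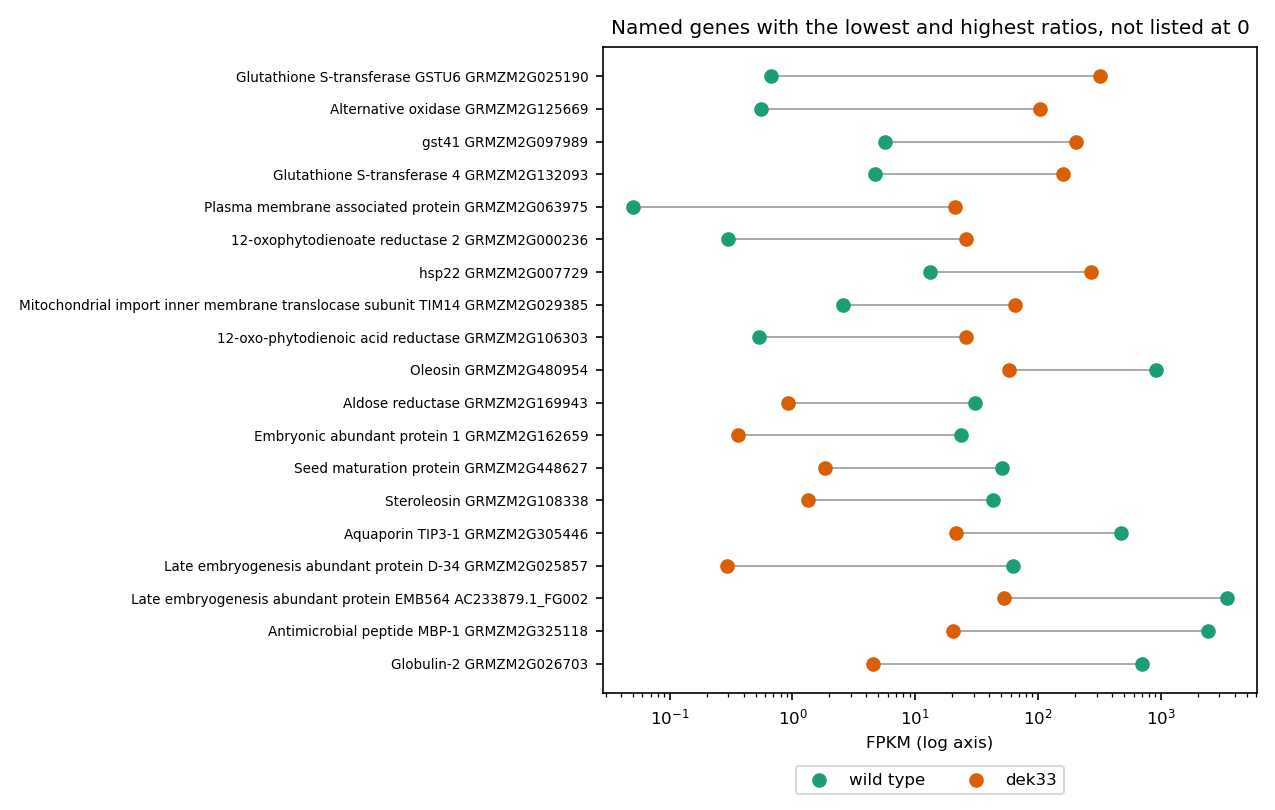
FPKM on a log axis of the named genes with the lowest and the highest ratios that are not listed at 0 in either library. Each line joins the wild type value and the dek33 value of 1 gene. GSTU6 lies at 0.667 in wild type and 322 in dek33, and globulin-2 at 700 and 4.53.

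Cell cycle and DNA replication genes had higher values in the dek33 library. Of 80 with an FPKM of at least 5, 51 were higher, 2 lower and 27 neither, and after centring 36 were higher and 2 lower. The median was 0.75 (interval 0.55 to 1.05), above each of the random lists. Histone H4 (GRMZM2G073275) had 154 in dek33 against 25.8 in wild type, and histone H3 (GRMZM2G451254) had 81.9 against 13.7. The word pattern of this list took in core histones, and every member named by the rule was a histone. The list was not tested without histones, so its median is not read as that of the other members. Cytosolic ribosomal protein genes had a median of 0.38, also above each random list, with 59 of 196 higher before centring and 5 after it. Heat shock genes had a median of 0.41 at percentile 100, with 15 of 25 higher before centring and 6 after it. Among them were hsp18c (GRMZM2G034157), at 54.0 against 5.09, and hsp82 (GRMZM5G833699), at 26.6 against 5.03. Endoplasmic reticulum chaperones did not stand apart, with a median of 0.13 at percentile 61.4. The pattern for that list took in other genes, among them an alpha zein (GRMZM2G353272, 2643 against 9362), and the corrected list of 19 in place of 28 members had a median of 0.03 at percentile 29.1.

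The median of starch synthesis genes lay within the middle 95% of random lists. The median of 36 genes was -0.04 at percentile 7.26. Of 30 at 5 FPKM or more, 3 were higher and 3 lower before centring, and 0 higher and 7 lower after it. Granule-bound starch synthase 1 (GRMZM2G024993), which makes amylose, had 3036 in dek33 against 3904 in wild type. The ADP-glucose pyrophosphorylase subunit bt2 (GRMZM2G068506) had 3700 against 1868, and sucrose synthase 2 (GRMZM2G152908) 79.6 against 219. Endosperm transcription factors had a median of 0.06 at percentile 44.7. Opaque-2 (GRMZM2G015534), a regulator of zein genes, had 466 against 245 and fl3 (GRMZM2G006585) 447 against 213. Amino acid and nitrogen metabolism genes had a median of 0.15 at percentile 67.4, or 0.02 at percentile 33.3 in the corrected list. The 2 expressed auxin synthesis genes had a median of -0.39 at percentile 23.4.

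Markers of other kernel tissues differed among themselves. Basal transfer layer markers, genes of the maternal-facing uptake cells, had a median of -1.21 over 11 genes (interval -1.61 to 0.01), below each of the random lists. Of 7 at 5 FPKM or more, 1 was higher, 1 lower and 5 neither before centring, and 1 was higher and 4 lower after it. BET1 (GRMZM2G082785) had 84.9 in dek33 against 177 in wild type and betl4 (GRMZM2G073290) 27.7 against 55.4, while betl10 (GRMZM2G091445) had 50.7 against 64.4. The higher one, mrpa1 (GRMZM2G113203, 5.83 against 1.28), is a transporter gene matched through the synonym MRP1, and without it the median was -1.30 (interval -1.61 to -0.78). Embryo and scutellum markers had a median of -2.26 over 6 genes, below each of the random lists but with an interval of -7.43 to 2.51 over members, with 3 of 5 lower and 1 higher (4 and 1 after centring). The higher one, a non-symbiotic hemoglobin with 15.5 against 1.13, was matched through a shared synonym, and without it the median of 5 genes was -3.16 at percentile 0.01. This list moved with the oil body and maturation genes, and 2 of its genes are also in the oil body list. Aleurone markers had a median of -0.25 at percentile 5.54, and embryo surrounding region markers one of -1.14 over 2 genes at percentile 3.28. Pericarp and green tissue markers stood at percentile 52.2 with a median of -0.07. Vascular and chalazal markers stood at percentile 95.3 with a median of 0.31. All members of that list named by the rule were fasciclin-like arabinogalactan proteins, taken in by a description word. The aleurone list likewise took in anthocyanidin glucosyltransferases by description. Whether such genes mark these tissues was not tested, so these medians are not read as tissue content.

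**Figure D3:**
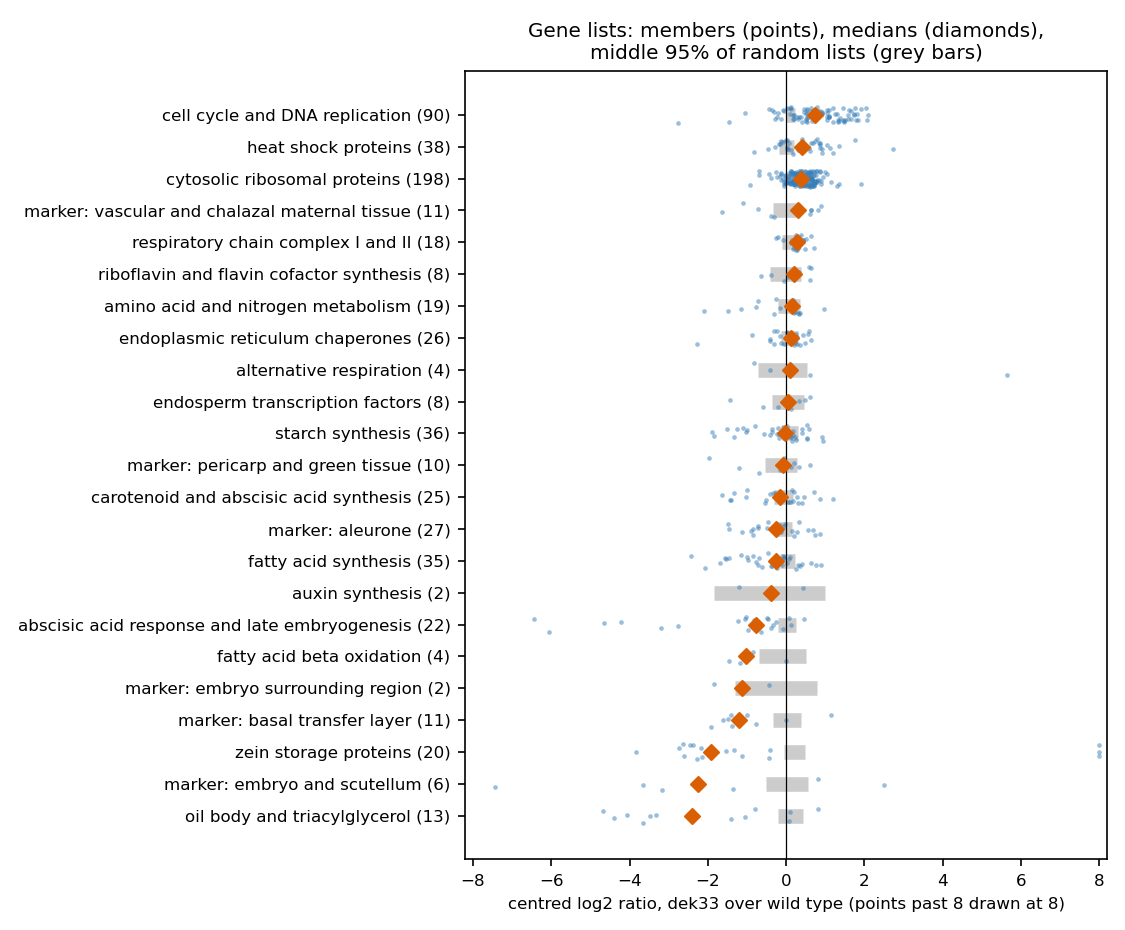
Centred log2 ratios (dek33 over wild type) of the members of the 23 gene lists, with the number of expressed members in brackets. Points are genes, diamonds are list medians, and grey bars span the middle 95% of random list medians. Oil body genes have the lowest median, -2.41, and cell cycle genes the highest, 0.75.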

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

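The alternatives with corrected lists and without genes or members listed at 0 were chosen after seeing the data. The counts of 2118 higher and 577 lower genes moved by over 1.5 times in most settings. A pseudocount of 5 gave 1038 and 347, a minimum of 20 FPKM 1203 and 247 (fewer genes tested), a 4-fold limit 219 and 196 (by construction), and no filter 894 lower genes. Scaling gave 632 and 974 when centred, 555 and 936 by trimmed mean of M values, 626 and 893 by upper quartile, and 575 and 919 by equal totals without zeins. Without genes listed at 0 the counts were 2095 and 562. The median log2 ratio of all genes was 0.52 with a pseudocount of 0.1, 0.26 with 5, 0.52 with a minimum of 5 FPKM, 0.22 without a filter, 0 when centred (by construction), 0.033 by trimmed mean and 0.049 without zeins. The scaling factors were 1.39 by trimmed mean and 1.37 without zeins, near the median factor of 1.36, so these 2 medians came out near 0. The pseudocount and filter settings involve no such factor.

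The uncentred list medians moved past their own intervals as follows, in the order centred, trimmed mean and without zeins: starch synthesis -0.0365, -0.0256 and -0.0122; complex I and II 0.27, 0.25 and 0.27; cell cycle 0.75, 0.78 and 0.79; ribosomal proteins 0.38, 0.36 and 0.38; endoplasmic reticulum chaperones 0.13, 0.12 and 0.13; heat shock proteins 0.41, 0.44 and 0.46. Basal transfer layer markers gave -1.21, -1.20 and -1.18. Fatty acid synthesis turned sign, to -0.26, -0.32 and -0.31, although its centred value stayed within its interval of -0.28 to 0.38. Centring moved carotenoid and abscisic acid synthesis to -0.16, and the trimmed mean moved zeins to -1.95. With a pseudocount of 5, cell cycle genes gave 0.98, ribosomal proteins 0.78 and heat shock proteins 0.51. A larger pseudocount draws every log2 ratio toward no difference by construction, most for low genes. All 9 corrected lists, and both lists with expressed members listed at 0, kept medians within the intervals of the lists as fixed, but the wide interval of the 6 embryo markers let their uncentred median move from -1.82 to -2.72. For lists too small for an interval the range of members stood in. The alternative respiration median was 3.05 over the 2 genes with at least 5 FPKM and 1.59 with a pseudocount of 0.1. It was -0.40 without zeins and -0.42 by trimmed mean, each equal to the value of GRMZM2G102349 at that setting. The settings thus changed which genes set this median. Of the 138 named genes, 0 changed sign past the 2-fold limit. Of them 15 no longer passed it with a pseudocount of 5 and 20 with either rescaling, while 3 came to pass it with each rescaling and 1 with a pseudocount of 0.1. No paired analysis was possible because each genotype has 1 sample. Alternatives that need replicates were not run, for the same reason. Those that need counts were not run because FPKM carries no read counts. Unknown depth leaves the precision of low values open.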

Other observations

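Lists and genes in this part were chosen after the values of the top genes had been seen, except where a test is named as written earlier. Cytosolic glycolysis genes had a median centred log2 ratio of 0.19 at percentile 80.0. Of 38 at 5 FPKM or more, 12 were higher and 2 lower before centring, and 7 higher and 5 lower after it. Among the abundant ones, the glyceraldehyde-3-phosphate dehydrogenase genes gpc4 (GRMZM2G176307) and gpc3 (GRMZM2G071630) had 4142 FPKM in dek33 against 566 in wild type and 1825 against 308. Enolase 1 (GRMZM2G064302) had 1844 against 296. Proteasome genes had a median of 0.35 at percentile 98.98, with 12 of 41 higher and 0 lower before centring, and 6 and 0 after it. Defence peptides and protease inhibitors had a median of -1.03, below each of the 10000 random lists, with 14 of 33 lower and 3 higher before centring, and 19 and 1 after it. Vacuolar aquaporins had a median of -0.62 over 7 genes (interval -4.84 to 0.08) at percentile 2.12. Of 5 at 5 FPKM or more, 3 were lower and 0 higher, before and after centring. The aquaporin list holds TIP3-1, which had been seen among the lowest genes. No version without genes already seen was made of it or of the defence list, so their percentiles partly restate such genes. Of 17 microRNA precursor loci, 11 were listed at 0 in the dek33 library and 3 in wild type. Over all genes the balance was the other way, 1330 in dek33 and 2022 in wild type, with 1 gene at 0 in both. Precursor zma-MIR168b had 248 in wild type and zma-MIR156e 61.9 in dek33, each listed at 0 in the other library. These loci are short (239639187 to 239639290 on chromosome 4 and 32121369 to 32121494 on chromosome 2). FPKM divides by length, so few fragments there can give a high value. With read counts unknown, no difference in precursors is read from these values. Within 10 Mb of PyrR, 11.3% of 133 genes with an FPKM of at least 5 passed 2-fold after centring, against 11.2% elsewhere.

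Of the tests below, those of low oxygen and of mitochondrial genes were written before their results were seen, and all others after. Most genes measured higher in the dek33 library, with a median log2 ratio of 0.44. A candidate explanation is that zein transcripts take a smaller part of that library, which raises every other gene in a unit scaled to the library. The part of summed FPKM outside zeins, used in place of the unknown part of fragments, gives a shift of 0.277, short of 0.44. Without the zeins listed at 0 in 1 library it gives 0.393, within 0.1 of the median, but this takes FPKM from the dek33 library alone. The 3 zeins listed at 0 in wild type would need 30309 FPKM there to bring the shift within 0.1 of the median, against 58699 in dek33 and 210087 for the other zeins in wild type. FPKM is scaled to fragments, so parts of summed FPKM do not measure the shift that a zein share would give. For that reason, and because the wild type values of those 3 zeins are unknown, the question stays open. Zein share and a different overall scaling by the authors cannot be told apart. Equal totals without zeins bring the median to 0.05, but would do so for a shift of any origin.

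Several oil body, embryo storage and maturation genes were lower in the dek33 library. A smaller zein share moves all other genes up by 1 common factor, so it does not account for the oil body list, which lay at percentile 0 of random lists under that same factor. Embryo tissue in the wild type library is a candidate source, since the source label is kernel and the tissue label endosperm. Over 12 expressed embryo identity regulators, of which 1 is in another list, the median was -0.673 (interval over members -1.11 to 0.02), at percentile 0.39 of random lists. Of these regulators 8 lay below the median of all genes and 4 above it. Their median lay between the bounds set, and wild type endosperm could express any of them. The most abundant, knotted-1-like 2 (GRMZM2G055243) and wox2A (GRMZM2G108933), went opposite ways, with 25.4 in dek33 against 33.4 and 19.0 against 9.60, so embryo tissue and a change in the endosperm cannot be told apart. An earlier developmental state of dek33 endosperm would go with cell cycle genes at percentile 100, but that value had been seen. Zeins and basal transfer layer markers lay at percentile 0, and starch synthesis and endosperm transcription factors at 7.26 and 44.7. What an earlier state predicts for these other lists was not set. No other age was analysed here, so an earlier state stays a hypothesis.

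1 alternative oxidase gene and some glutathione transferase and mitochondrial membrane genes, such as the outer membrane porin vdac2 (GRMZM2G115049, 233.8 against 16.3), had far higher values in the dek33 library. The other abundant alternative oxidase gene did not, and the complex I and II list lay at percentile 84.3. Low oxygen during growth or harvest is argued against by 6 fermentation genes, with a median of -0.175, an upper bound of 0.14 and alcohol dehydrogenase 1 (GRMZM2G442658) at 672 against 690, but gpc4, gpc3, enolase 1 and non-symbiotic hemoglobin (GRMZM2G067402), also known to respond to low oxygen, were 7.31, 5.93, 6.23 and 13.7-fold higher in dek33, so a part in those genes stays open. The 37 expressed mitochondrial import, prohibitin and chaperonin genes not seen earlier stood at percentile 100 with a median of 0.63, with 23 of 35 higher and 0 lower before centring and 6 and 0 after it, in line with a wider difference of that group as a hypothesis. The glutathione transferase family stood at percentile 99.3, and without the 3 members seen earlier at 69.19, with 8 of 17 higher and 1 lower before centring and 5 and 2 after it, so whether the difference is of the family or of some members cannot be told apart. A lower flavin supply in dek33 is a biological explanation that the design names and that was not tested.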
